A study of Mus musculus with 8 samples.

How the data were processed

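Poly(A)-selected RNA from total brain of 5 Cstf2 D50A mutant mice and 3 wild-type littermates, 50 days old, was sequenced, per the labels. The strain background is C57BL/6NCrl with 4 backcross generations, and libraries were prepared with an NEBNext Ultra RNA kit, per the labels' protocols. The authors deposited raw read counts per gene, with no normalization, in 1 table of 25815 genes. Per the submitters' processing notes, CASAVA 1.8, STAR 2.5, HTSeq 0.6.1 and DESeq2 2 were used with the genome build mm10; the notes give no order. The annotation release and strand setting are not given in the sources used here. Each gene in the table has a total of at least 1 count over the libraries, and 1402 genes have exactly 1.

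Groups were taken from the genotype label of each sample. The labels name separate animals and no batch, so the p-values measure the spread between single libraries of these mice. That spread cannot separate differences between mice from differences in RNA or in the tissue taken. Counts were tested with edgeR's quasi-likelihood test in R 4.3.3 (edgeR 4.0.16) after filterByExpr and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 8 libraries entered the fit, with no covariate, and 16810 genes were tested. CPM values use TMM-scaled library sizes, and log2 CPM adds a prior count of 2. The SE of a log2 fold change is its size over the square root of the F statistic.

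The test, the alternatives, the rule for named genes and 37 gene lists were fixed before the data were examined. Of the lists, 35 with at least 3 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry. A list said to rise or fall as a set passed camera at this preset. Estimated correlations were far above it for several lists, such as 0.826 for cerebellum and 0.566 for axon guidance. For the other 2 lists, sex-linked and substrain-variable genes, values of some members are given. The rule names Cstf2 and Cstf2t, then the 10 genes with the smallest unadjusted p where fewer than 10 pass, and from each list the 4 tested members with the smallest unadjusted p. Examples are printed for lists that passed the set test and for lists tied to RNA 3' end formation or with calls adjusted over the list alone. Other genes, including members of the cerebellum list beyond those 4, were named after their values were seen.

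Alternatives were DESeq2 1.42.0, whose adjusted p was missing for 5815 genes, limma-voom with sample quality weights, other scaling factors, no filter, a filter of at least 1 CPM in 3 libraries, removal of mitochondrially encoded and hemoglobin genes, a surrogate variable (sva 3.50.0), each library left out in turn and a threshold of 0.1. Robust quasi-likelihood fitting and a fit without D50A 1 and D50A 3 were added after seeing the data.

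Gene positions, transcript lengths, GC content and 3' UTR lengths came from GENCODE M21, which uses the mm10 assembly, and 25484 gene identifiers matched. Length and GC trends used genes with a mean log2 CPM above 2. The tests were tried on simulated counts with known changes: for 5 against 3 libraries (16810 genes) edgeR recovered 2%, 6%, 76% and 90% of genes changed 1.5-, 2-, 4- and 8-fold, with 4 unchanged genes called, and DESeq2 recovered 14%, 38%, 94% and 100% with 60 unchanged genes called. For D50A 2, 4 and 5 against WT (16591 genes) edgeR recovered 80% of genes changed 1.5-fold and 100% of genes changed 2-fold, with 15 unchanged genes called. Changed genes were taken only from those with higher mean counts, so these rates do not cover genes with few counts. Counts were drawn independently for each gene, with no library set apart. Depth ran from 13675945 to 24802272 counts per library.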

Results

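RNA from the brains of 8 mice was sequenced at postnatal day 50. The question set by the design was whether an alanine in place of aspartate in CSTF2, a cleavage stimulation factor subunit that binds RNA near polyadenylation sites, alters brain transcript levels. The mutant group, D50A, held 5 libraries and the wild-type littermate group, WT, held 3. Total counts per library were 24802272, 18999799, 13675945, 17975329 and 19269722 for D50A 1 to 5, and 20551906, 19284799 and 16455364 for WT 1 to 3. The labels give the tissue as total brain and name no sex, litter or batch. Library numbers follow the order of deposit and pair no animals.

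The libraries differed in ways that the genotype label does not separate. D50A 3 had 11.9% of its counts on mitochondrially encoded genes, against 4.08% to 5.14% in the other 7 libraries. Its deviation from the WT mean was lower for longer transcripts across 12438 genes, with a Spearman rho of -0.56. In D50A 1, 2, 4 and 5 the rho was -0.23, -0.16, -0.31 and -0.16. WT 1 to 3 had 0.1, -0.26 and 0.1. For this and the GC trend below, each WT library was set against the mean of the other WT libraries. Genes are not independent replicates, so these rho values describe the libraries. The first principal component held 79.9% of the variance. The highest Pearson correlation of D50A 3 with another library was 0.888, and each of the others reached at least 0.992 with some library. D50A 1 had the highest rho with GC content, 0.66, against -0.45 to 0.36 elsewhere. Chi-square statistics per degree of freedom for pairs within a group ran from 3.36 to 457, so no pair looked like copies of 1 library.

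**Figure D1:**
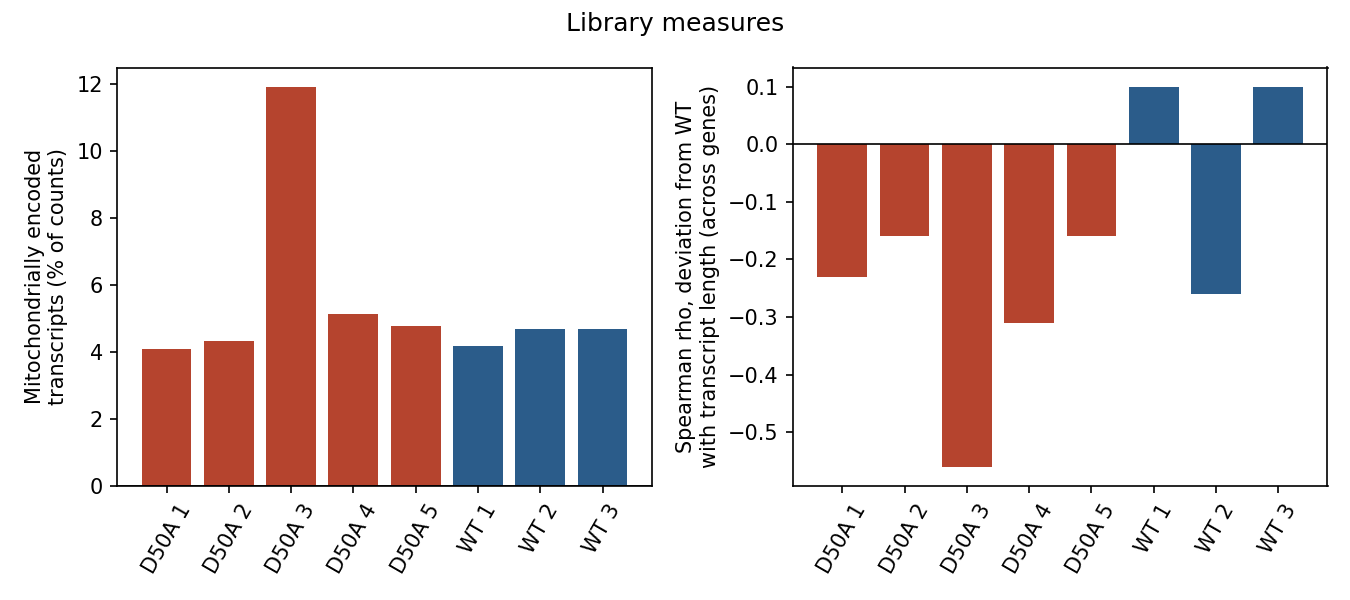
Left, percent of counts on mitochondrially encoded genes in each library. Right, Spearman rho across genes between the deviation from the WT mean and transcript length, with each WT library set against the other WT libraries. Red bars are D50A and blue bars are WT libraries; D50A 3 stands at 11.9% and -0.56.

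No difference in the edited gene itself was detected between the genotypes. Cstf2 (ENSMUSG00000031256), a protein-coding gene on the plus strand of chromosome X from 134059187 to 134086819 in mm10, had 108 ± 25.3 CPM (SD, n = 5) in D50A and 127 ± 6.66 CPM (SD, n = 3) in WT. Its log2 fold change was -0.23 with an SE of 0.22 (edgeR quasi-likelihood test, adjusted p = 0.84). The D50A libraries held 2695, 2407, 711, 2263 and 2608 Cstf2 counts, and D50A 3 gave the lowest level, 65.8 CPM. Without D50A 3 the log2 fold change was -0.09. Its autosomal paralog Cstf2t (ENSMUSG00000053536, chromosome 19, 31082837 to 31087069) had 64.9 ± 4.95 CPM (SD, n = 5) against 69.8 ± 6.23 CPM (SD, n = 3), with a log2 fold change of -0.1 and an SE of 0.13 (edgeR adjusted p = 0.84). A missense change need not alter the gene count, so these values do not check the labels.

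No single gene passed the threshold in the comparison of 5 D50A with 3 WT libraries. edgeR called 0 genes higher and 0 lower of 16810 tested, with 420 at an unadjusted p under 0.05 and a smallest adjusted p of 0.837. DESeq2 called 31 higher and 6 lower, and limma-voom with sample quality weights called 315 higher and 202 lower. The cerebellum list, whose mean was high in D50A 2 to 5 only, held 9 of the DESeq2 and 10 of the limma-voom higher calls. In simulated data for this comparison, edgeR recovered 6% of genes changed 2-fold and 76% of genes changed 4-fold, all taken from genes with higher counts. DESeq2 called 60 unchanged genes in those data and edgeR called 4. Without D50A 1, edgeR called 26 genes higher and 0 lower. Without D50A 1 and D50A 3 together, a choice made after seeing the data, it called 558 higher and 507 lower of 16591 tested. D50A 1 also differs from D50A 2, 4 and 5 in cerebellar transcripts, so leaving it out favours calls among those genes. Every D50A library lay above every WT library for 541 genes and below for 712, where chance gives 1.8%, or 300 genes, on average in each direction. Genes move together in these libraries, so a single split can lie far from that average. This count was not made for other splits, so it does not show an excess.

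The 10 genes with the smallest unadjusted p did not pass by edgeR; DESeq2 called 8 of the 10 and limma-voom all 10. In each of them all 5 D50A libraries lay on one side of all 3 WT libraries. The genes were picked by p in this same comparison, so that separation is favoured by the choice and adds no support. Gm17732 had 0.241 ± 0.125 CPM (SD, n = 5) in D50A and 1.46 ± 0.137 CPM (SD, n = 3) in WT, a log2 fold change of -2.56 with an SE of 0.36 (edgeR adjusted p = 0.84). Tgm4, a transglutaminase, was at 0.266 ± 0.12 CPM against 0.999 ± 0.0785 CPM. Gm17116, annotated as antisense, was at 0.237 ± 0.145 CPM against 1.39 ± 0.255 CPM. Bub1b, a mitotic checkpoint kinase, was at 1.42 ± 0.352 CPM against 3.59 ± 0.834 CPM, with a log2 fold change of -1.31 and an SE of 0.25. Pkd2l1, an ion channel gene, was at 1.15 ± 0.248 CPM against 2.51 ± 0.189 CPM. The other 5 were higher in D50A. Cnpy1 was at 51.6 ± 36.1 CPM against 1.28 ± 0.289 CPM, with 2.1 CPM in D50A 1 and 29.8 to 86.5 CPM in D50A 2 to 5. Stap2 was at 5.34 ± 1.6 CPM against 1.96 ± 0.222 CPM. Hotairm1, an antisense transcript of the HoxA cluster, was at 0.708 ± 0.148 CPM against 0.21 ± 0.0504 CPM. RP23-269P7.1 was at 0.813 ± 0.253 CPM against 0.243 ± 0.0433 CPM. Pax2, a developmental transcription factor gene, had 16, 32, 3, 21 and 21 counts in D50A 1 to 5 and 0, 1 and 1 in WT. Because the strand setting of the counting is not given in the sources used here, reads of Gm17116 and Hotairm1 cannot be told from those of overlapping genes.

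**Figure D2:**
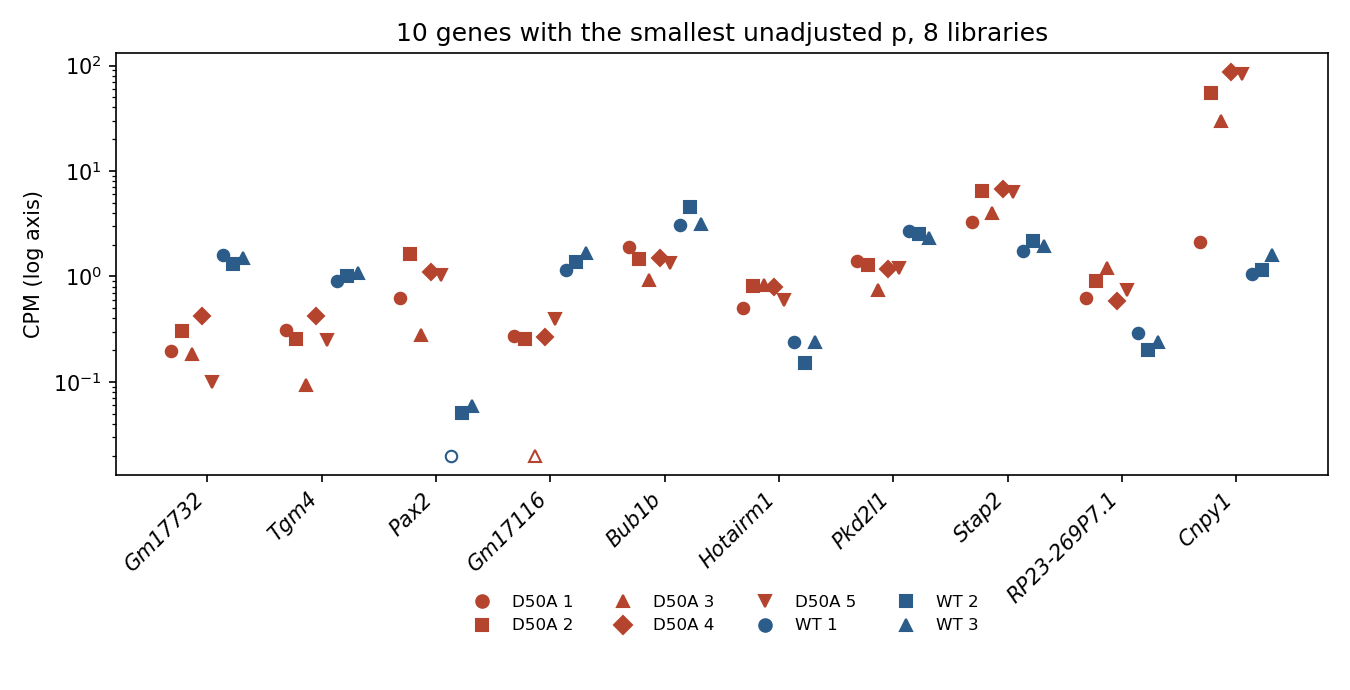
CPM on a log axis for the 10 genes with the smallest unadjusted p, 1 symbol per library, red for D50A and blue for WT. Open symbols at the foot mark libraries with a count of 0; Cnpy1 is at 2.1 CPM in D50A 1 and at 29.8 CPM or more in the other D50A libraries.

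Cerebellar transcripts were far higher in D50A 2 to 5 than in D50A 1 and the WT libraries. Gabra6, a GABA receptor subunit gene of cerebellar granule cells, had 53.2, 108, 108 and 103 CPM in D50A 2 to 5, and 0 CPM in D50A 1 and WT 1, 0.304 CPM in WT 2 and 0.119 CPM in WT 3. Cbln3, a granule cell gene, had 118 to 239 CPM in D50A 2 to 5 and 0.623 CPM in D50A 1, against 0.818 to 1.37 CPM in WT. The 12 list members rose as a set (camera, adjusted p = 6.1e-16), with adjusted p = 0.6 with an estimated correlation. Over all genes tested, edgeR called no member, DESeq2 called 9 higher and limma-voom 10 higher; 11 passed by edgeR adjusted over the list alone. Cbln1 had a log2 fold change of 2.59 with an SE of 0.57, Fat2 of 6.2 with an SE of 1.38, Cbln3 of 7.2 with an SE of 1.64, and Slc1a6, a glutamate transporter gene of Purkinje cells, of 1.05 with an SE of 0.25. The mean log2 CPM of the list was 2.27 in D50A 1 and 5.61 to 6.08 in D50A 2 to 5, against 2.28 to 2.47 in WT. In the fit without D50A 1 and D50A 3, all 12 members passed by edgeR over all genes tested (camera adjusted p = 1.9e-24, and adjusted p = 0.2 with an estimated correlation).

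**Figure D3:**
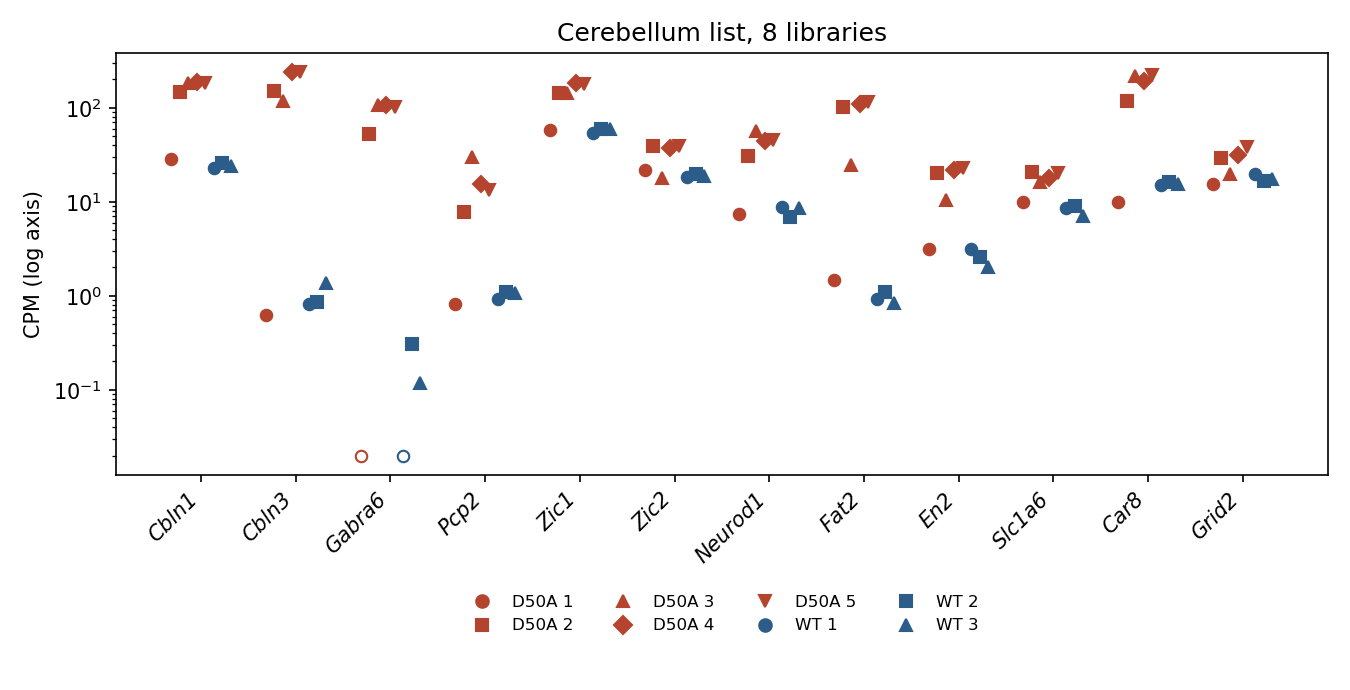
CPM on a log axis for the 12 members of the cerebellum list, 1 symbol per library, red for D50A and blue for WT, with open symbols at the foot for a count of 0. D50A 1 lies beside the WT libraries, with Cbln3 at 0.623 CPM, while D50A 2 to 5 lie higher for most members.

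Axon guidance, glutamatergic synapse, cortex and hippocampus, and X-linked intellectual disability genes fell as sets, although edgeR and DESeq2 called none of their members over all genes tested and edgeR none adjusted over the list alone. limma-voom called 3 axon guidance genes lower, 4 glutamatergic synapse genes higher and 2 lower, and 1 lower in each of the other 2 lists. Axon guidance genes (41 tested) had a median log2 fold change of -0.33 (camera adjusted p = 4.5e-06, and adjusted p = 0.6 with an estimated correlation). Nrp1, a semaphorin co-receptor, was at 37.3 ± 1.75 CPM (SD, n = 5) against 46.7 ± 3.64 CPM (SD, n = 3), and Unc5d, a netrin receptor gene, was at 42.7 ± 11.6 CPM against 59.6 ± 0.838 CPM. Glutamatergic synapse genes (39 tested) had a median of -0.27 (camera adjusted p = 0.001, and adjusted p = 0.64 with an estimated correlation). Among them Grm5, a metabotropic glutamate receptor gene, was at 201 ± 25.3 CPM against 252 ± 9.51 CPM, and Homer3, a scaffold gene, went the other way at 23.1 ± 7.55 CPM against 10.3 ± 1 CPM. Homer3 was at 10.4 CPM in D50A 1 and 22.3 to 29.5 CPM in D50A 2 to 5, the libraries with high cerebellar transcripts. Cortex and hippocampus markers (14 tested) had a median of -0.32 (camera adjusted p = 0.011, and adjusted p = 0.6 with an estimated correlation), with C1ql2 at 10.5 ± 0.859 CPM against 13.3 ± 0.36 CPM. X-linked intellectual disability genes (40 tested) had a median of -0.16 (camera adjusted p = 0.017, and adjusted p = 0.6 with an estimated correlation), with Cnksr2 at 178 ± 52.4 CPM against 250 ± 11.7 CPM. D50A 3 was the lowest library for all 4 lists, for example at 3.9 mean log2 CPM for axon guidance against 5.45 to 5.72 in the other 7 libraries. Without D50A 3 the adjusted p of camera was 0.00024 for axon guidance, 0.0072 for the glutamatergic synapse, 0.0013 for cortex and hippocampus and 0.13 for the X-linked genes, which also had 0.11 without D50A 1. The medians without D50A 3 were smaller, at -0.15, -0.09, -0.17 and -0.07 in that order, and without D50A 1 and D50A 3 they were -0.16, -0.12, -0.17 and -0.03. The cerebellum list mean was 5.61 to 6.08 in D50A 2 to 5 and 2.28 to 2.47 in WT, so these lists were compared between libraries that differ in cerebellar content.

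Ribosomal and respiratory chain genes rose as sets by camera at the preset correlation, with D50A 3 far above the rest. The estimated correlation was 0.995 for ribosomal proteins, 0.906 for oxidative phosphorylation and 0.953 for mitochondrially encoded genes. The small p-values below therefore rest on the preset. Cytosolic ribosomal protein genes (74 tested) had a median log2 fold change of 1.18 (camera adjusted p = 2.1e-09, and adjusted p = 0.64 with an estimated correlation). Their mean log2 CPM was 9.99 in D50A 3 and 7.11 to 7.42 in the other 7 libraries, and Rps14 had 836 ± 1280 CPM (SD, n = 5) in D50A against 247 ± 33.6 CPM (SD, n = 3). Nuclear-encoded oxidative phosphorylation genes (74 tested) had a median of 0.77 (camera adjusted p = 1.4e-11, and adjusted p = 0.6 with an estimated correlation), with Uqcrq at 239 ± 277 CPM against 99.3 ± 7.59 CPM. Mitochondrially encoded genes (12 tested) had a median of 0.56 (camera adjusted p = 0.012, and adjusted p = 0.64 with an estimated correlation), with mt-Co3 at 675 ± 1000 CPM against 185 ± 41.3 CPM. No member of these 3 lists passed by edgeR or limma-voom over all genes tested, or by edgeR adjusted over the list alone. DESeq2 called none either, but gave no p for 65 of the ribosomal, 29 of the oxidative phosphorylation and 5 of the mitochondrially encoded genes. Without D50A 3 the adjusted p of camera was 0.062 for ribosomal proteins, 1.2e-08 for oxidative phosphorylation and 0.8 for mitochondrially encoded genes, and the medians were smaller, at 0.05, 0.11 and 0 in that order. Without D50A 1 and D50A 3 they were 0.09, 0.15 and 0.06.

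Mature oligodendrocyte, interferon and reactive glia, monoaminergic and histone lists also rose as sets, each with a call that depends on single libraries or on D50A 1 and D50A 3 together. edgeR and DESeq2 called none of their members over all genes and edgeR none adjusted over the list alone; limma-voom called 1 oligodendrocyte and 1 interferon and reactive glia gene higher. Astrocyte and microglia lists did not pass (camera adjusted p = 0.34 for each). Mature oligodendrocyte genes (14 tested) had a median log2 fold change of 0.36 (camera adjusted p = 0.0097, and adjusted p = 0.6 with an estimated correlation), with the myelin gene Mobp at 2170 ± 1190 CPM (SD, n = 5) against 1380 ± 102 CPM (SD, n = 3). The oligodendrocyte list mean was 8.58 log2 CPM in D50A 3, and the median was 0.11 without D50A 3 and 0.14 without D50A 1 and D50A 3 (camera adjusted p = 0.053). Interferon and reactive glia genes (17 tested) had a median of 0.42 (camera adjusted p = 0.0012, and adjusted p = 0.6 with an estimated correlation). The class I histocompatibility gene H2-D1 was at 50.8 ± 7.37 CPM against 38.6 ± 3.01 CPM. The interferon list mean was 3.46 log2 CPM in D50A 3 and 2.98 in D50A 1, against 2.57 to 2.76 in the other 6 libraries. The median of that list was 0.19 without D50A 3, and 0.07 without D50A 1 and D50A 3 (camera adjusted p = 0.38). Monoaminergic neuron genes (8 tested) had a median of 0.48 (camera adjusted p = 0.017, and adjusted p = 0.6 with an estimated correlation), with Tph2, an enzyme gene of serotonin synthesis, at 7.62 ± 1.22 CPM against 4.33 ± 2.88 CPM. WT 1 was low, with a monoaminergic list mean of 0.96 log2 CPM against 1.95 and 2.46 in WT 2 and WT 3 and with Tph2 at 1.06 CPM, and the adjusted p of camera was 0.078 without WT 1, 0.2 without D50A 1 and 0.068 without D50A 2. Replication-dependent histone genes (14 tested), whose mRNAs end without a poly(A) tail, had a median of 0.32 (camera adjusted p = 0.025, and adjusted p = 0.64 with an estimated correlation). Hist1h1e was at 1.05 ± 0.334 CPM against 0.53 ± 0.15 CPM, and the histone list mean was 2.72 log2 CPM in D50A 3 against 1.27 to 1.72 in the other 7 libraries. The histone list had an adjusted p by camera of 0.14 without D50A 3, 0.083 without D50A 1, 0.45 without WT 3, 0.1 with the stricter filter on low counts and 0.09 with the surrogate variable. Its median was 0.07 without D50A 3. The libraries were made from poly(A)-selected RNA, so most histone mRNA was outside the measurement.

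Pituitary hormone genes fell as a set (4 tested, camera adjusted p = 0.029, and adjusted p = 0.6 with an estimated correlation), and 3 members passed by edgeR adjusted over the list alone while 0 passed over all genes by edgeR or limma-voom. DESeq2 gave no p for 3 of the 4, Gh, Prl and Pomc. The difference rested on WT 2, which held 595 CPM of growth hormone (Gh), 104 CPM of prolactin (Prl) and 136 CPM of Pomc. WT 1 held 12 CPM of Gh and WT 3 held 0, and the D50A libraries held 0.0779 to 3.6 CPM. Without WT 2 the Pomc log2 fold change was 0.26 (edgeR adjusted p = 0.93). The adjusted p of camera was 0.77 without WT 2, 0.073 to 0.11 without D50A 1, 2, 3 or 5, and 0.21 with the surrogate variable.

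The remaining 22 lists did not pass, with camera adjusted p from 0.068 to 0.94. The 22 cleavage and polyadenylation factors had a median log2 fold change of -0.07 (camera adjusted p = 0.39), and none passed over all genes by edgeR, DESeq2 or limma-voom, or by edgeR adjusted over the list alone. Fip1l1, a subunit of the polyadenylation machinery, was at 57.1 ± 6.84 CPM (SD, n = 5) against 65.1 ± 3.32 CPM (SD, n = 3), and Clp1 was at 8.65 ± 2.51 CPM against 7.11 ± 1.17 CPM. The 20 histone pre-mRNA processing and Integrator genes had a median of -0.05 (camera adjusted p = 0.72), with Ints12 at 12.6 ± 4.63 CPM against 8.48 ± 0.609 CPM (edgeR adjusted p = 0.84, limma-voom adjusted p = 0.046); limma-voom called no other member of that list. The 19 termination and nuclear RNA decay factors had a median of 0.02 (camera adjusted p = 0.57), and the 29 neuronal RNA-binding regulators had a median of -0.09 (camera adjusted p = 0.096). Among neural progenitor genes (16 tested, camera adjusted p = 0.34) the median was -0.18 and the mean 0.08, and 2 members rose by edgeR adjusted over the list alone, 0 over all genes; DESeq2 and limma-voom each called 2 higher over all genes. Pax6 was at 26.9 ± 6.57 CPM against 12.6 ± 1.89 CPM, and Neurod1, also a cerebellum list member, was at 36.8 ± 18.8 CPM against 8.13 ± 1.05 CPM. Both were highest in D50A 2 to 5, the libraries with high cerebellar transcripts. Pax6 had 24.8 to 32.7 CPM there, 16.5 CPM in D50A 1 and 10.6 to 14.3 CPM in WT. Neurod1 had 30.9 to 56.4 CPM there, 7.32 CPM in D50A 1 and 6.94 to 8.9 CPM in WT. In the ependyma and motile cilia list (10 tested, camera adjusted p = 0.34) 1 member fell by edgeR adjusted over the list alone, Spag17, at 0.452 ± 0.135 CPM against 1.06 ± 0.146 CPM.

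Genes beside Cstf2 on the X chromosome were compared with the rest because the colony was backcrossed for 4 generations, which can leave a linked segment. Of 79 tested genes within 10 Mb of Cstf2, 0 passed the edgeR threshold, as did 0 of 16620 other genes, which leaves nothing to compare. At an unadjusted p under 0.05 there were 3 of 79 genes, or 3.8%, against 2.49% of the others (Fisher's exact test, two-sided, p = 0.45). DESeq2 and limma-voom calls were not compared by position.

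Sex-linked genes placed all 8 libraries alike, as from male mice. Xist, the transcript of the inactive X chromosome, had 0 to 8 counts per library, and the Y-linked gene Ddx3y had 1223 to 1751 counts. Nnt, which is deleted in part in some C57BL/6 substrains, had 22.5 to 35.1 CPM in D50A and 32.2 to 37 CPM in WT.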

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

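All tests of explanations in this part were chosen after the results were seen. Of 54 measures of the 5 D50A libraries, 23 had a library far from the other 4 by Dixon's criterion, 19 of them D50A 3; chance flags about 1 in 20, and the measures are not independent.

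D50A 3 stood apart in genes with a count (20404), in the mitochondrial share (11.9%) and in the share of the 10 most abundant genes (13.7%). Its mean log2 CPM was far above the other D50A libraries for replication-dependent histones (2.72), astrocytes (7.9), mature oligodendrocytes (8.58), microglia (5.62), striatum (6.42), mitochondrially encoded genes (11.45), oxidative phosphorylation (8.19) and cytosolic ribosomal proteins (9.99). It was far below them for histone pre-mRNA processing (3.87), neuronal RNA-binding regulators (6.18), the glutamatergic synapse (5.6), axon guidance (3.9), X-linked intellectual disability genes (5.66), oligodendrocyte precursors (4.28), cortex and hippocampus (4.63) and the gene Gm17116 (-3.25). Mitochondrial and hemoglobin transcripts alone displacing the rest would leave the other genes in proportion. With those transcripts removed, the highest correlation of D50A 3 with another library was 0.887, against at least 0.983 among the other 7. That correlation was 0.888 with them, so the removal added little to what was already seen. Loss of long transcripts from fragmented RNA is a candidate explanation: the rho with transcript length was -0.56, and the next lowest library had -0.31. RNA integrity values were not used here, and no biological explanation was tested, since the other 4 libraries share the genotype.

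D50A 1 stood apart in the cerebellum list (2.27 mean log2 CPM), in Cnpy1 (1.14 log2 CPM) and in mural cells and meningeal fibroblasts (3.99). In D50A 1, 10 of 12 cerebellum list members were lower than in each of D50A 2 to 5, as they were in every WT library. Presence of cerebellar tissue in those 4 samples and its absence from the other 4 is a candidate explanation. The WT libraries held at most 0.304 CPM of Gabra6, a gene of a cell type that normal whole brain contains in abundance. That 10 members moved together is the pattern itself and does not tell causes apart. A wrong label on D50A 1 is argued against: among genes chosen as lower in D50A 2, 4 and 5 than in a pair of WT libraries, D50A 1 lay below the WT library left out in at least 81.8% of genes. An effect of the genotype on its own is argued against, since it would leave wild-type whole brain with these transcripts. The cerebellum list mean was only 2.28 to 2.47 log2 CPM in WT, with Cbln3 at 0.818 to 1.37 CPM. An added effect of the genotype on cerebellar transcripts cannot be told apart from tissue content, because no WT library held them at a high level. Only 1 D50A library (D50A 1) was at the WT level, and it may have lost the tissue.

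The ependyma and motile cilia list stood apart in D50A 4, at 1.72 mean log2 CPM.

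Outside the pituitary list, 11 genes were at least 2-fold lower in D50A 2, 4 and 5 than in WT (edgeR, adjusted over all genes), from -2.38 for Gm17732 to -1.02 for Adam8 on the log2 scale. Dilution by cerebellar RNA is argued against, since the lowest of 23 forebrain list members, Wfs1, was at -0.43. The genes were chosen again with each WT library left out, giving 9, 12 and 11 genes; D50A 1 lay below the WT library left out in 9, 11 and 9 of them, and D50A 3 in at least 88.9%. For D50A 1, lists matched on GC content and level did as well in at most 189 of 10000 draws, which argues against its GC trend. No such lists were drawn for D50A 3, and none was matched on transcript length, so its share has no reference value. These choices also share most of their genes, with 8, 9 and 8 of them among the 11 above. A difference that follows the D50A label is a hypothesis that the D50A 1 values go with, while the D50A 3 share cannot decide. Whether such a difference comes from the D50A codon, other alleles that differ between the colony's genotypes, or the tissue taken was not tested. Xlr3b, 1 of the 11, belongs to a family of near-identical copies whose reads cannot be assigned with certainty.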

How the results depend on the processing

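The fit without D50A 1 and D50A 3 and the robust fit were chosen after seeing the data. No paired analysis was possible because the labels give no shared replicate numbers. The Cstf2 log2 fold change kept its direction and stayed short of the threshold under all alternatives run, from -0.3 to -0.03. The count of 0 genes higher became 31 with DESeq2, 315 with limma-voom and sample quality weights, 1 with the surrogate variable, 0 to 26 with a library left out (26 without D50A 1) and 558 without D50A 1 and D50A 3. The count of 0 genes lower became 6 with DESeq2, 202 with limma-voom, and 507 without D50A 1 and D50A 3, and was 0 with each single library left out. limma-voom gave D50A 3 a sample weight of 0.0272 and D50A 1 of 0.355, against at least 1.83 elsewhere; the cause was not tested for these tools. All 31 and 6 DESeq2 calls were also called without D50A 1 and D50A 3. So were 302 of the 315 higher and 183 of the 202 lower limma-voom calls, so the calls of these tools are not separate from that fit. Both counts stayed at 0 with other scaling, other filters, mitochondrial and hemoglobin genes left out, robust fitting and a threshold of 0.1. The 13 lists became 0 with an estimated correlation and 0 with fry, which do not take a preset correlation, and were 9 to 17 with a library left out, 11 of 34 with the stricter filter on low counts (histones lost, pituitary with too few members tested), 14 with the surrogate variable (histones and pituitary lost, 3 gained) and 9 without D50A 1 and D50A 3. Without D50A 1 and D50A 3, 3 of 79 genes near Cstf2 passed, 3.8% against 6.43% of the other genes (Fisher's exact test, two-sided, p = 0.49). Among named genes, log2 fold changes that had not passed changed sign as follows. With limma-voom, Gap43 was at -0.02, Lum at -0.03, Rarres2 at -0.1, Hbb-bs at -0.03, Hbb-bt at -0.05, Hba-a2 at -0.05 and Tnnt1 at -0.18. Without D50A 3, Gap43 was at -0.01, Rarres2 at -0.1, Hbb-bs at -0.04, Hbb-bt at -0.11, Hba-a2 at -0.05 and Tnnt1 at -0.14. Without D50A 1 and D50A 3, Gap43 was at -0.01, Nr4a3 at 0.01, Lum at -0.02, Rarres2 at -0.07, Hbb-bt at -0.04, Hba-a2 at -0.07 and Tnnt1 at -0.18. Tnnt1 was at -0.02 with the surrogate variable, and without WT 2 Pomc was at 0.26 and Tshb at 0.29. The cause was not tested except for WT 2, which held most of the pituitary transcripts. With a library left out, the range was -0.01 to 0.39 for Gap43, -0.1 to 0.96 for Rarres2, -0.04 to 1.25 for Hbb-bs, -0.11 to 1.25 for Hbb-bt, -0.05 to 0.8 for Hba-a2, -3.64 to 0.26 for Pomc, -1.32 to 0.29 for Tshb and -0.14 to 0.64 for Tnnt1. Named genes that newly passed numbered 14 with DESeq2, 36 with limma-voom, 1 with the surrogate variable, 6 without D50A 1 and 49 without D50A 1 and D50A 3. Genes near 1 CPM, such as Tgm4 with 1 to 8 counts per D50A library, are limited by depth.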

Other observations

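The tests in this part were chosen after the results were seen. In the fit without D50A 1 and D50A 3, all 12 cerebellum genes rose, with a median log2 fold change of 2.96 (camera adjusted p = 1.9e-24, and adjusted p = 0.2 with an estimated correlation), and cortex and hippocampus genes had a median of -0.17. The lists below are compared between libraries that differ in cerebellar content. In that fit 7 lists no longer passed by camera: interferon and reactive glia (adjusted p = 0.38), mature oligodendrocytes (0.053), monoaminergic neurons (0.053), histones (0.4), mitochondrially encoded genes (0.17), X-linked intellectual disability genes (0.29) and pituitary (0.29). In that fit fry called 4 lists. Cerebellum was higher (adjusted p = 0.00031 by fry), and striatum (0.0039), cortex and hippocampus (0.02) and oligodendrocyte precursors (0.031) were lower. Camera with an estimated correlation called 0 lists. By camera at the preset correlation, 3 lists passed that had not passed over all 8 libraries. Striatum genes (9 tested) fell as a set (camera adjusted p = 0.00065, and adjusted p = 0.2 with an estimated correlation), with a median log2 fold change of -0.18, and Rgs9, a regulator of striatal G protein signalling, was at -0.24 with an SE of 0.06 (edgeR adjusted p = 0.019). Oligodendrocyte precursor genes fell too (10 tested, camera adjusted p = 0.031, and adjusted p = 0.46 with an estimated correlation), with Pdgfra at -0.35 and an SE of 0.06 (edgeR adjusted p = 0.001). GABAergic genes fell as a set (28 tested, camera adjusted p = 0.044, and adjusted p = 0.6 with an estimated correlation), although 3 members rose and 4 fell over all genes tested. Pvalb, a calcium buffer gene of fast-spiking interneurons and Purkinje cells, rose by 1.51 with an SE of 0.1 (edgeR adjusted p = 4e-08), Calb2 by 0.82 (adjusted p = 3.2e-07) and Gabrd by 0.41 (adjusted p = 0.0032), while Npy was at -0.34 (adjusted p = 0.0092). The 507 genes called lower had a median log2 fold change of -0.32 and the 558 called higher 0.52; 14 of the former and 133 of the latter changed at least 2-fold.

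Other splits of the samples were counted for each number of called genes. All 56 splits of the 8 libraries into 5 and 3 gave at least the 0 genes called for the genotypes, so that count tests nothing; the highest other split gave 10. At an unadjusted p under 0.05, 24 of 56 splits gave at least the real 420 genes, and the highest gave 2939, with D50A 3, D50A 4 and D50A 5 as the group of 3. Chance is therefore not excluded for the unadjusted number, and the high value points to a structure of the samples. Without D50A 1, only the real split, 1 of 35, gave 26 genes, and the highest other gave 4, but D50A 1 was left out with its cerebellar level known, so the split count says nothing about chance. For D50A 2, 4 and 5 against WT, 10 splits are too few for a share under 0.05. The real split gave 1065 genes and the highest other gave 1. D50A 1 and D50A 3 were left out after the data were seen, and the groups then differ in cerebellar transcripts. The real split was therefore favoured in advance.

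A factor of 3' end processing could shift genes by 3' UTR length. The rho per library between the deviation from the mean of all 8 libraries and 3' UTR length, across 12059 genes that are not independent replicates, averaged 0.12 ± 0.26 (SD, n = 5) in D50A and 0.28 ± 0.08 (SD, n = 3) in WT. The low D50A mean came from D50A 3, the library with the strongest trend with transcript length, at -0.28, and D50A 1, at -0.02; D50A 2, 4 and 5 were at 0.25, 0.25 and 0.37, and WT 1 to 3 at 0.21, 0.25 and 0.37. A two-sided exact permutation test gave p = 0.46, and the smallest p that the 56 permutations allow is 0.018, so no shift was shown. Gene counts do not measure which poly(A) site was used.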
